A study of Mus musculus with 12 samples.

How the data were processed

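RNA was measured from mouse bone marrow cultures grown with GM-CSF, a growth factor of myeloid cells, on Affymetrix GeneChip Mouse Gene 1.0 arrays, with 1 array per sample. Per the labels' protocols, C57B/6 mouse marrow, taken from leg bones, was cultured for 6 days with 20 ng/ml GM-CSF. The cells labelled GM-DC (dendritic cells) and GM-MF (macrophages) were left unstimulated or received 10 ng/ml lipopolysaccharide (LPS), a bacterial Toll-like receptor 4 ligand, for 4 hours. The 4 groups held 3 arrays each, 12 in all, and the labels name no batch, scan date or shared culture.

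The table held log2 values deposited by the authors, made with RMA in R 3.0.2 per the submitters' processing notes. The base of the logarithm is not written in the labels and was taken as 2 from the range of the table, 1.18 to 13.7. RMA settings are not stated. The values were used as deposited, with no further scaling and no filter. The highest value of each array lay between 13.5 and 13.7 and the array medians between 4.41 and 4.54. The raw scanner files were not used here, so no background call was made for any probe set, and a low value was not read as absence. A fold against a value under the array medians is a ratio of signals, the lower one not shown to lie above background. For arrays the number per group, 3, limits the precision. No genome build is named, so no coordinates are given.

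Of 35556 probe sets, 21789 were paired with 1 gene symbol, 1621 with several and 12146 with none in the annotation of the platform. Entrez identifiers of 21698 of those with 1 symbol were found in the RefSeq gene table of assembly GRCm38.p6, 91 were not, and 0 symbols changed. Where a gene had several probe sets, as for 999 genes, the one with the highest mean over all 12 arrays was kept, which left 19938 genes.

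Differences were tested with limma: lmFit with 4 group means on all 12 arrays, contrasts.fit, and eBayes without trend, with 8 residual degrees of freedom. The fit gave 5 comparisons: GM-DC minus GM-MF without LPS, GM-DC minus GM-MF with LPS, LPS minus unstimulated in GM-DC, LPS minus unstimulated in GM-MF, and the difference of these LPS responses (the interaction). The test is two-sided, and p-values were adjusted by Benjamini-Hochberg over the 19938 genes of each comparison. A gene was called at an adjusted p under 0.05, and a second count asked also for a log2 difference of at least 1, which is 2-fold. Standard errors after the sign ± are those of the moderated limma fit. Values marked SE are the SD over genes divided by the square root of their number.

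Before the data were examined, 32 gene lists with 576 entries were written, of which 528 were measured, and 33 of 539 symbols stood in more than 1 list. They were dendritic cell core, macrophage core, dendritic cell maturation and migration, MHC class II presentation, costimulation, cytokines, chemokines, interferon-stimulated genes, NF-kB targets and feedback, Toll-like receptors and adaptors, phagocytic, scavenger and lectin receptors, complement and integrins, lysosome, cholesterol synthesis and uptake, cell cycle, glycolysis, tricarboxylic acid cycle, inflammasome, alternative activation, myeloid transcription factors, and immediate early and handling stress. Markers of other cells that the cultures could hold made up the others: conventional DC type 1, conventional DC type 2, plasmacytoid DC, monocyte, neutrophil and granule, mast cell and basophil, eosinophil, B cell, T and NK cell, stromal and erythroid markers. Each list was tested with limma's fry, whose p-value asks whether the members move, on balance, one way and does not compare the list with other genes. The p-values were adjusted over the 32 lists of each comparison. Limma's camera, which compares a list with the other genes, was run with a preset correlation of 0.01 between members and with an estimated correlation.

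The genes named were fixed by a rule written before the data were examined. Per comparison these were the 8 called genes with the largest positive and the 8 with the largest negative difference whose 3 values per group did not overlap (10% of genes separate 3 arrays from 3 by chance; for the interaction overlap was not asked), leaving out clone and model names. Per list they were up to 4 called members with the largest difference, up to 2 per direction where members moved both ways, or up to 2 with the highest mean where none was called. A set of lineage markers, cytokines and chemokines was also fixed in advance. Genes outside the rule are said to be chosen after their values were seen.

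Replicate numbers 1 to 3 repeat across the groups, and the labels do not say that they stand for a shared culture. After each gene was centred on its group means, the correlations of arrays of the same number ran from 0.119 to 0.363 between GM-DC with and without LPS and from 0.104 to 0.257 between GM-MF with and without LPS. Arrays of different numbers ran from -0.25 to 0.164 and from -0.216 to 0.0254, and 1 of 3 and 3 of 3 arrays correlated best with their own number. As all 6 lie above 0.1, the numbers were read as pairs for both LPS comparisons, with the ranges overlapping in GM-DC. Across cell types they ran from -0.168 to 0.0117 without LPS and from -0.0047 to 0.156 with LPS, and were not read as pairs. The main fit holds no term for the pairs, and fits with a replicate block were run as alternatives.

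The same code was tested on simulated data of 19938 genes, of which 261 were given known changes in each comparison. Noise was drawn with the moderated variances of the limma fit. Genes changed 2-fold were recovered at 100% for GM-DC against GM-MF without LPS, 96% with LPS, 100% for LPS in GM-DC, 98% for LPS in GM-MF and 92% for the interaction, and genes changed by 0.5 on the log2 scale at 36%, 36%, 40%, 42% and 10%. False calls made up 5.5%, 2.13%, 5.05%, 3.92% and 3.66% of the calls. In each comparison 2 of 2 shifted lists were found. Of 27 unchanged lists 1 was called for LPS in GM-MF, and fry called 0 in each of the other comparisons. The simulated genes were drawn independently of each other and without pairs of arrays. False list calls were therefore not tested for members that move together. The data gave many more calls than the simulation, 1514 to 7228 per comparison, so the cut on the unadjusted p was stricter in the simulation. Its recovery of small changes is therefore not an estimate for the data.

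Alternatives were averaged probe sets, all 35556 probe sets, genes with at least 3 arrays above the table median (11706 genes), genes with a mean above the median of gene means (9969 genes), median centring, quantile normalization, cyclic loess, eBayes with trend and robust, array weights, fits on only the arrays compared, a replicate block, treat against 1.5-fold, and leaving out each array in turn. A replicate block within each cell type was added after the data were seen. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.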

Results

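The data were 12 expression arrays of mouse bone marrow cells grown with GM-CSF, 3 each of dendritic cells (GM-DC) and macrophages (GM-MF), unstimulated or after 4 hours with 10 ng/ml LPS. Values are log2 expression as deposited, levels are given with the SD over 3 arrays, and differences with the standard error of the limma fit after the sign ±, n = 3 arrays per group. Arrays of a group correlated at 0.993 to 0.996 across genes, and the median SD of a gene within a group was 0.121 to 0.138. The p-values measure only the spread between these arrays, which may be technical, because the labels do not say whether replicates came from separate mice or cultures. The first principal component, with 76.5% of the variance, parted GM-DC from GM-MF, and the next, with 10.4%, parted arrays with LPS from those without.

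**Figure D1:**
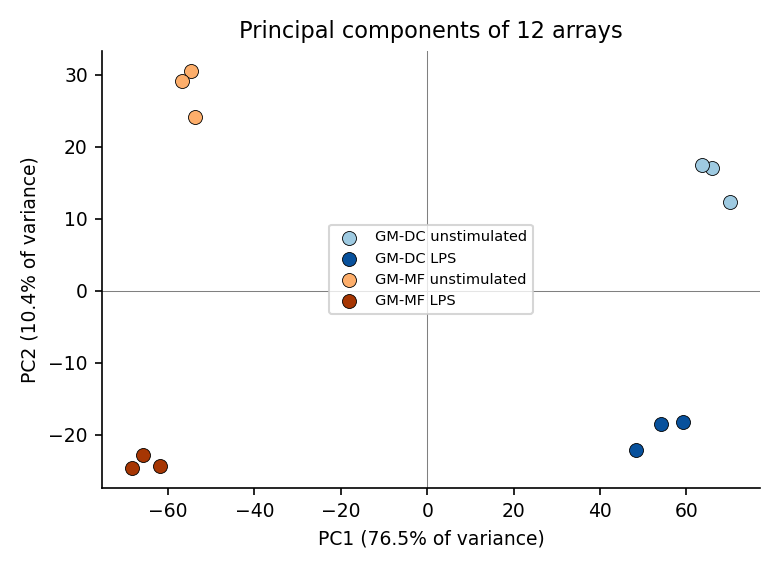
The first 2 principal components of the log2 values of 12 arrays, each point being 1 array and each colour 1 of the 4 groups. Component 1 (76.5% of the variance) separates GM-DC from GM-MF, and component 2 (10.4%) separates LPS from unstimulated arrays in both cell types.

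The comparison of GM-DC with GM-MF before LPS asks how the dendritic cells and macrophages that grow in the same kind of culture differ. GM-DC held the transcripts of migratory, mature dendritic cells and GM-MF those of macrophages with high expression of interferon-induced genes. The lists of conventional DC type 1 and type 2 markers had lower mean levels in GM-DC. Among the genes highest in GM-DC were Stat4 (193-fold, log2 7.59 ± 0.13, adjusted p = 6.37e-14), a transcription factor of interleukin-12 signalling, and Fscn1 (119-fold, log2 6.89 ± 0.32), an actin-bundling protein of mature dendritic cells. Ccr7 (33.5-fold, log2 5.07 ± 0.26), the chemokine receptor that guides dendritic cells to lymph nodes, Flt3 (20.2-fold, log2 4.34 ± 0.15), a growth factor receptor of dendritic cell precursors, and Zbtb46 (4.32-fold, log2 2.11 ± 0.12), a transcription factor of classical dendritic cells, were also higher in GM-DC. GM-MF expressed more Csf1r (-4.64 ± 0.12), the receptor of the macrophage growth factor M-CSF, Fcgr1 (28.0-fold, log2 -4.81 ± 0.13), a high-affinity Fc receptor, Itgam (26.2-fold, log2 -4.71 ± 0.17), the integrin CD11b, and Mertk (10.4-fold, log2 -3.37 ± 0.16), a receptor for the uptake of dying cells. The MHC class II gene H2-Ab1, at 11.80 ± 0.00667 in GM-DC and 12.03 ± 0.0349 in GM-MF, did not pass (adjusted p = 0.0547). Itgax, which encodes CD11c, was higher in GM-MF (-2.20 ± 0.27).

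Of 19938 genes, 6827 passed, 3593 higher and 3234 lower in GM-DC (52.6% higher, against 48.7% after cyclic loess, which turns the balance), and 8088 had an unadjusted p under 0.05. A difference of at least 2-fold was found for 2533 genes, 1134 higher and 1399 lower, and of at least 4-fold for 950. The other genes at the top in GM-DC were Ceacam15 (6.46 ± 0.15), Ramp3 (6.40 ± 0.21), Scin (5.98 ± 0.16), Serpinb6b (5.90 ± 0.22), Strip2 (5.70 ± 0.14) and Il2ra (5.64 ± 0.18), the last being the alpha chain of the interleukin-2 receptor. Those at the top in GM-MF included Saa3 (-6.75 ± 0.31), an acute phase protein, and Acod1 (-6.62 ± 0.20), the enzyme that makes itaconate.

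Lists of lineage genes parted the cell types. Counts are of measured members, and counts adjusted over the list alone are added where they differ. For dendritic cell core genes 24 of 31 members were higher in GM-DC, 3 were lower and 4 did not pass, median log2 2.06, fry adjusted p = 5.6e-09. P2ry10 (5.05 ± 0.23) was among those higher, and Itgb7 (-1.54 ± 0.11) and Fgl2 (-1.09 ± 0.22) among those lower. For maturation and migration genes 20 of 23 members were higher in GM-DC, 1 was lower and 2 did not pass, median 2.85, fry adjusted p = 2.46e-09, the member that was lower being the chemokine Ccl17 (-0.71 ± 0.17). For macrophage core genes 2 of 35 members were higher in GM-DC, 30 were lower and 3 did not pass, median -1.82, fry adjusted p = 9.76e-08. Tlr7, a receptor for single-stranded RNA, was lower in GM-DC (-5.33 ± 0.18), at 3.36 ± 0.37, under the array medians, while Ltc4s, which makes leukotriene C4, was higher (2.48 ± 0.19). Costimulation genes were mostly higher in GM-DC: 7 of 12 members were higher in GM-DC, 2 were lower and 3 did not pass (7 higher and 3 lower adjusted over the list alone), median 0.88, fry adjusted p = 1.82e-05, adjusted p = 0.29 with an estimated correlation. Cd83 (4.33 ± 0.21), Tnfsf4 (2.97 ± 0.17) and Cd86 (1.51 ± 0.11) were among those higher and the inhibitory ligand Cd274 (-0.91 ± 0.11) was lower. MHC class II presentation went both ways: 4 of 12 members were higher in GM-DC, 4 were lower and 4 did not pass (4 higher and 5 lower adjusted over the list alone), median 0.0622, fry adjusted p = 0.00078, adjusted p = 0.902 with an estimated correlation. H2-Eb2 (3.34 ± 0.15) and H2-Oa (1.62 ± 0.11) were higher and Marchf1 (-2.47 ± 0.16), a ligase that removes class II from the surface, lower. That call was lost in a fit on only the arrays compared (adjusted p = 0.0958).

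**Figure D2:**
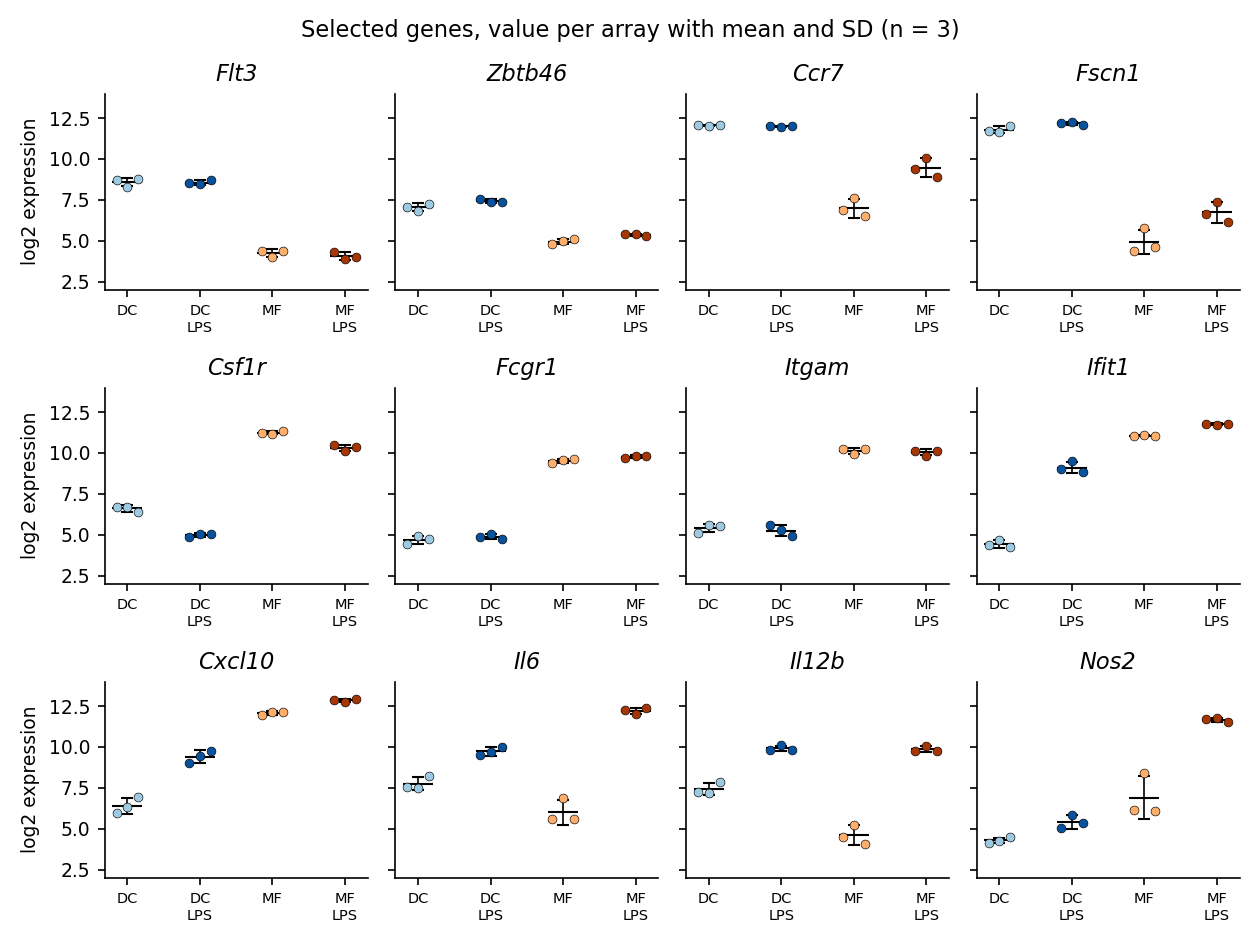
Log2 expression of 12 named genes in every array, with bars for the mean and SD of 3 arrays per group. Flt3, Zbtb46, Ccr7 and Fscn1 lie higher in GM-DC, Csf1r, Fcgr1 and Itgam higher in GM-MF, and Ifit1, Cxcl10, Il6, Il12b and Nos2 change with LPS, except Nos2 in GM-DC, which did not pass. The call of Cxcl10 in GM-MF was lost without GM-MF LPS replicates 1 and 3 and GM-MF unstimulated replicate 1 (adjusted p 0.0553 to 0.0787).

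Interferon-stimulated genes, which cells switch on in response to interferons, differed by a median of -4.08 between the cell types: 28 of 30 members were lower in GM-DC and 2 did not pass (29 lower adjusted over the list alone), fry adjusted p = 5.6e-09. Ifit3 (205-fold, log2 -7.68 ± 0.18), Rtp4 (170-fold, log2 -7.41 ± 0.21), Ifit2 (147-fold, log2 -7.20 ± 0.17) and Ifit1 (98.2-fold, log2 -6.62 ± 0.15) were lower in GM-DC, as was Samd9l (117-fold, log2 -6.87 ± 0.17) outside the list. Chemokines were also lower in GM-DC: 2 of 20 members were higher in GM-DC, 16 were lower and 2 did not pass (3 higher and 16 lower adjusted over the list alone), fry adjusted p = 9.29e-09. Among them were Cxcl10 (-5.67 ± 0.21), a ligand that draws T cells, Ccl3 (-5.06 ± 0.14) and Ccl2 (-4.63 ± 0.20). Ccl22 (3.47 ± 0.23) and Ccl5 (1.16 ± 0.12) were the higher ones. Of cytokines 4 of 20 members were higher in GM-DC, 9 were lower and 7 did not pass, fry adjusted p = 3.97e-05, adjusted p = 0.421 with an estimated correlation. Il1a (-5.58 ± 0.20), Tnf (-5.05 ± 0.27) and Il1b (-4.57 ± 0.18) were lower and Il12b (2.84 ± 0.24) and Il6 (1.74 ± 0.29) higher in GM-DC before LPS. Inflammasome genes followed: 9 of 10 members were lower in GM-DC and 1 did not pass, fry adjusted p = 3.04e-07. They included Nlrp3 (-4.17 ± 0.18), a sensor of cell damage, and Casp4 (-2.24 ± 0.14), a caspase that binds LPS.

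Uptake and digestion genes were higher in GM-MF. For phagocytic, scavenger and lectin receptors 1 of 28 members was higher in GM-DC, 24 were lower and 3 did not pass, median -3.36, fry adjusted p = 5.43e-09. Clec4e (-6.72 ± 0.27), a receptor for mycobacterial glycolipids, and Msr1 (-5.55 ± 0.12), a scavenger receptor, were lower in GM-DC and Ly75 (2.40 ± 0.13), the endocytic receptor DEC-205, was higher. For complement and integrins 12 of 14 members were lower in GM-DC and 2 did not pass, fry adjusted p = 1.08e-09. Among them were C5ar1 (-4.72 ± 0.19) and C1qb (-4.53 ± 0.12). For lysosomal genes 25 of 25 members were lower in GM-DC, fry adjusted p = 7.01e-08, adjusted p = 0.0508 with an estimated correlation. Among them were the proteases Ctsk (-4.72 ± 0.19) and Ctsl (-3.26 ± 0.14) and the membrane protein Cd68 (-3.37 ± 0.10). Toll-like receptors and adaptors were split: 4 of 17 members were higher in GM-DC, 12 were lower and 1 did not pass, fry adjusted p = 4.29e-08, adjusted p = 0.0694 with an estimated correlation. Tlr8 (-4.75 ± 0.20) was lower and Traf6 (1.38 ± 0.12) and Tlr9 (0.97 ± 0.15) higher. In the alternative activation list 3 of 15 members were higher in GM-DC, 8 were lower and 4 did not pass, fry adjusted p = 8.45e-09. Arg1 (-5.07 ± 0.20), which breaks down arginine, and Chil3 (-5.02 ± 0.20) were lower and Cdh1 (1.63 ± 0.14) higher. Glycolysis genes were mostly lower in GM-DC: 2 of 14 members were higher in GM-DC, 9 were lower and 3 did not pass (2 higher and 10 lower adjusted over the list alone), fry adjusted p = 0.00078, adjusted p = 0.394 with an estimated correlation. Hk2 (-3.11 ± 0.28) and Hk3 (-2.63 ± 0.17) were lower and Pfkfb3 (2.49 ± 0.24) higher. The other member counted as higher, Hk1, changed sign with probe sets averaged (-0.15). For the cell cycle 7 of 27 members were higher in GM-DC, 16 were lower and 4 did not pass, fry adjusted p = 8.69e-05, adjusted p = 0.263 with an estimated correlation. Mki67 (-2.21 ± 0.15) was lower and Mcm6 (2.05 ± 0.15) higher.

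Marker lists of other cells were compared as well. Monocyte markers were lower in GM-DC: 1 of 7 members was higher in GM-DC and 6 were lower, fry adjusted p = 3.63e-08. The chemokine receptor Ccr2 (-4.90 ± 0.13) was among those lower. Conventional DC type 2 markers were mixed: 3 of 10 members were higher in GM-DC, 5 were lower and 2 did not pass, fry adjusted p = 6.43e-06, adjusted p = 0.263 with an estimated correlation. Mgl2 (-4.31 ± 0.23) and Clec10a (-3.39 ± 0.23) were lower and Irf4 (3.20 ± 0.21) higher. The type 2 list had a mean level of 5.42 ± 0.0857 in GM-DC and 6.23 ± 0.0779 in GM-MF. Conventional DC type 1 markers had a mean level of 6.28 ± 0.0483 in GM-DC and 6.79 ± 0.0579 in GM-MF. That list passed (fry adjusted p = 0.00348), but lost its call under 3 of 19 alternatives. Among these were camera with an estimated correlation and fry without 1 of the arrays (adjusted p = 0.172). Of plasmacytoid DC markers 2 of 8 members were higher in GM-DC, 3 were lower and 3 did not pass, fry adjusted p = 0.0015, adjusted p = 0.93 with an estimated correlation, with Spib (4.53 ± 0.23) higher and a median of -0.00857 against the direction of the test. For neutrophil and granule markers 2 of 15 members were higher in GM-DC, 5 were lower and 8 did not pass, fry adjusted p = 0.00101, adjusted p = 0.431 with an estimated correlation. The collagenase Mmp8 (-5.20 ± 0.31) was lower and Prtn3 (2.03 ± 0.15) higher. Immediate early and handling stress genes, which can rise while cells are prepared, were lower in GM-DC: 2 of 13 members were higher in GM-DC, 8 were lower and 3 did not pass (3 higher and 8 lower adjusted over the list alone), fry adjusted p = 1.44e-05, adjusted p = 0.263 with an estimated correlation. Egr2 (-3.15 ± 0.14) and Egr1 (-2.64 ± 0.13) were lower and Hspa1a (0.91 ± 0.13) higher. For T and NK cell markers 2 of 9 members were higher in GM-DC, 1 was lower and 6 did not pass (fry adjusted p = 0.19, and 0.0346 among genes with a mean above the median). Thy1 (1.30 ± 0.20) was 1 of those higher. For eosinophil markers 1 of 5 members was higher in GM-DC, 1 was lower and 3 did not pass (fry adjusted p = 0.548). For B cell markers 1 of 8 members was higher in GM-DC, 1 was lower and 6 did not pass (fry adjusted p = 0.0116, adjusted p = 0.747 with an estimated correlation), a call lost among genes with at least 3 arrays above the table median (adjusted p = 0.817). For myeloid transcription factors 9 of 24 members were higher in GM-DC, 10 were lower and 5 did not pass (10 higher and 10 lower adjusted over the list alone) (fry adjusted p = 0.413, and 0.033 with median centring, 0.0146 among genes with a mean above the median and 0.0204 without GM-MF unstimulated replicate 2). For erythroid markers, of the 4 measured members 4 did not pass, with 0 of them at an unadjusted limma p under 0.05 (fry adjusted p = 0.882), with Slc4a1 at 4.59 ± 0.11 in GM-DC and 4.73 ± 0.24 in GM-MF.

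Fry passed 24 of 32 lists, 17 passed camera with the preset correlation and 10 with an estimated correlation. Those 10 were dendritic cell core, macrophage core, maturation and migration, chemokines, interferon-stimulated genes, phagocytic receptors, complement and integrins, inflammasome, alternative activation and monocyte markers.

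The same comparison with LPS asks which differences hold once both cell types are stimulated. Most did: 1912 genes differed at least 2-fold in the same direction with and without LPS, 616 only without and 655 only with LPS (which does not test those differences against each other), and the differences correlated at 0.884 across genes, which are not independent replicates. The 5 genes that differed at least 2-fold in opposite directions, all but Il6 and Lrrc32 named after their values were seen, were Cd82 (-1.46 without and 1.94 with LPS), Ethe1 (-1.08 without and 1.07 with LPS), Il6 (1.74 without and -2.49 with LPS), Lrrc32 (-2.64 without and 1.12 with LPS) and Serpinb1a (1.41 without and -1.37 with LPS). Il6 was higher in GM-DC before LPS and lower after it (-2.49 ± 0.29, adjusted p = 4.59e-06). With LPS the genes furthest toward GM-DC were again Stat4 (6.63 ± 0.13) and Ramp3 (5.91 ± 0.21). They also included Sema7a (5.46 ± 0.13), Tmem176b (5.35 ± 0.17) and Tmem176a (5.34 ± 0.14). Toward GM-MF they were Ch25h (98.2-fold, log2 -6.62 ± 0.19, adjusted p = 1.44e-12), which makes 25-hydroxycholesterol, Rnase2a (-6.58 ± 0.24), Ms4a6d (-6.31 ± 0.18), U90926 (-6.31 ± 0.18), Mmp8 (-6.25 ± 0.31), Bst1 (-6.25 ± 0.17), Nos2 (-6.24 ± 0.44), the inducible nitric oxide synthase, and Pdpn (-6.01 ± 0.16).

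With LPS 7228 genes passed, 4165 higher and 3063 lower in GM-DC (57.6% higher, against 48.7% after cyclic loess, which turns the balance), 8406 had an unadjusted p under 0.05, and 2572 differed at least 2-fold, 1277 higher and 1295 lower, 928 of them at least 4-fold. Cytokines were lower in GM-DC: 3 of 20 members were higher in GM-DC, 14 were lower and 3 did not pass, median -2.41, fry adjusted p = 5.32e-07, adjusted p = 0.0652 with an estimated correlation. Among them were Il1a (-5.29 ± 0.20), Il1b (-4.79 ± 0.18), Il12a (-4.02 ± 0.21), Ifnb1 (-3.51 ± 0.22) and the inhibitory Il10 (-3.35 ± 0.21). Il23a (1.53 ± 0.20) and Ebi3 (1.34 ± 0.13) were higher in GM-DC, while Il12b, at 9.93 ± 0.15 in GM-DC and 9.87 ± 0.18 in GM-MF, did not pass (adjusted p = 0.905). For interferon-stimulated genes 29 of 30 members were lower in GM-DC and 1 did not pass, median -2.11, fry adjusted p = 1.62e-07, adjusted p = 0.0575 with an estimated correlation. Among them were Iigp1 (-5.31 ± 0.15) and Ifit3 (-4.79 ± 0.18). For chemokines 1 of 20 members was higher in GM-DC, 14 were lower and 5 did not pass (1 higher and 15 lower adjusted over the list alone), fry adjusted p = 1.04e-08. Among them were Ccl12 (-5.63 ± 0.28) and Cxcl3 (-4.87 ± 0.35). For costimulation genes 7 of 12 members were higher in GM-DC, 3 were lower and 2 did not pass (8 higher and 3 lower adjusted over the list alone), fry adjusted p = 1.74e-05, adjusted p = 0.307 with an estimated correlation. Cd70 (5.10 ± 0.27) was higher. For NF-kB targets and feedback genes 5 of 23 members were higher in GM-DC, 12 were lower and 6 did not pass (6 higher and 12 lower adjusted over the list alone), fry adjusted p = 0.000127, adjusted p = 0.426 with an estimated correlation. Relb (1.75 ± 0.12) was higher and Acod1 (-4.70 ± 0.20) lower. Cholesterol synthesis and uptake genes were higher in GM-DC with LPS: 16 of 19 members were higher in GM-DC, 2 were lower and 1 did not pass, median 0.87, fry adjusted p = 5.1e-05, adjusted p = 0.265 with an estimated correlation. Pmvk (2.40 ± 0.14) and Idi1 (2.39 ± 0.12) were higher and Insig1 (-0.54 ± 0.14) lower. Of mast cell and basophil markers 1 of 10 members was lower in GM-DC and 9 did not pass (fry adjusted p = 0.000552, adjusted p = 0.401 with an estimated correlation), Hdc being the only one to pass (-3.53 ± 0.17). Fry passed 24 of 32 lists, camera 19 with the preset correlation and 6 with an estimated one (dendritic cell core, maturation and migration, chemokines, phagocytic receptors, complement and integrins, and alternative activation).

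**Figure D3:**
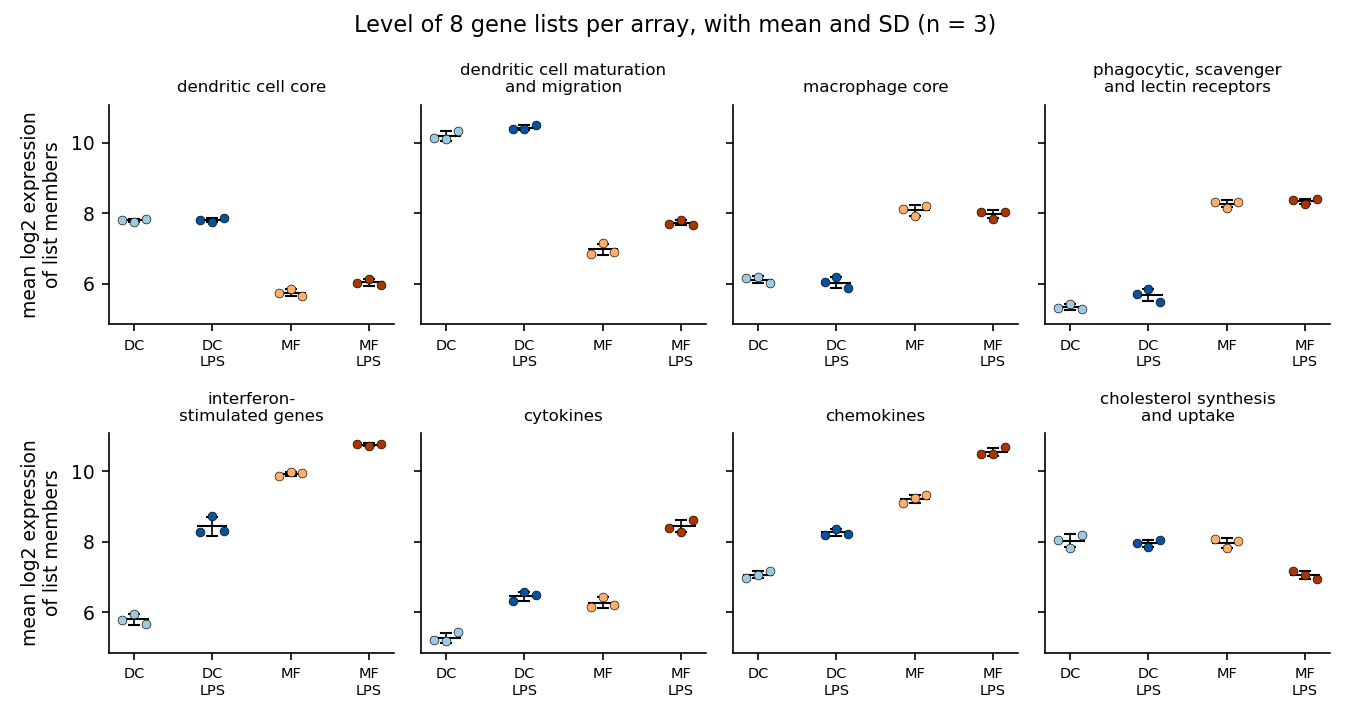
Mean log2 expression of the measured members of 8 gene lists in every array, with bars for the mean and SD of 3 arrays per group. Interferon-stimulated genes lie at 5.79 ± 0.15 in unstimulated GM-DC, 8.43 ± 0.27 in GM-DC with LPS, 9.93 ± 0.0526 in unstimulated GM-MF and 10.76 ± 0.0343 in GM-MF with LPS.

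LPS in GM-DC was compared with no LPS to ask how the dendritic cells respond. The 8 largest rises included the interferon-stimulated genes Ifit1 (25.3-fold, log2 4.66 ± 0.15, adjusted p = 1.35e-10), Irgm1 (23.3-fold, log2 4.54 ± 0.23) and Ifit2 (20.1-fold, log2 4.33 ± 0.17), and Samd9l (19.8-fold, log2 4.31 ± 0.17), Slfn1 (20.5-fold, log2 4.36 ± 0.26) and Ifi207 (19.9-fold, log2 4.32 ± 0.16) outside the list. Among them were also Ifi205 (4.64 ± 0.15) and the chemokine Ccl3 (19.0-fold, log2 4.25 ± 0.14). Costimulatory Cd70 (3.81 ± 0.27), Tnfsf9 (2.97 ± 0.22), Cd40 (2.16 ± 0.20) and Cd86 (1.16 ± 0.11) rose as well. The cytokines Tnf (6.99-fold, log2 2.81 ± 0.27), Il23a (6.47-fold, log2 2.69 ± 0.20), Il12b (5.63-fold, log2 2.49 ± 0.24) and Il6 (3.96-fold, log2 1.98 ± 0.29) rose, while Il12a did not pass (0.37 ± 0.21, adjusted p = 0.389). Ccr7, at 12.05 ± 0.0455 before LPS, did not pass (-0.0549 ± 0.26, adjusted p = 0.958). Nor did H2-Ab1 (0.0334 ± 0.0848, adjusted p = 0.91).

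In GM-DC 1938 genes passed, 1042 up and 896 down, 3884 had an unadjusted p under 0.05, and 415 changed at least 2-fold, 329 up and 86 down, 98 of them at least 4-fold. With a test against 1.5-fold (limma's treat) 268 genes passed. The largest falls were Tmem37 (7.05-fold, log2 -2.82 ± 0.21, adjusted p = 5.18e-07), Id3 (4.79-fold, log2 -2.26 ± 0.18), an inhibitor of helix-loop-helix transcription factors, Atp6v0d2 (-1.93 ± 0.19), a subunit of the proton pump, Pld4 (-1.91 ± 0.33), Tmem51 (-1.89 ± 0.16), Cldn1 (-1.88 ± 0.21), Lpar6 (-1.76 ± 0.11) and Ephx1 (-1.72 ± 0.23). Csf1r (3.08-fold, log2 -1.62 ± 0.12) also fell.

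For interferon-stimulated genes 28 of 30 members rose and 2 did not pass (29 up adjusted over the list alone), median log2 2.89, fry adjusted p = 7.36e-07. For chemokines 10 of 20 members rose, 1 fell and 9 did not pass, median 0.53, fry adjusted p = 2.61e-06. Among them were Ccl2 (3.55 ± 0.20) and Cxcl10 (3.01 ± 0.21). For cytokines 13 of 20 members rose and 7 did not pass (13 up and 1 down adjusted over the list alone), median 1.17, fry adjusted p = 6.28e-05. These 3 lists were also the ones that held in camera with an estimated correlation, and fry passed 12 of 32 and camera with the preset correlation 9. For costimulation 7 of 12 members rose and 5 did not pass (8 up and 1 down adjusted over the list alone), fry adjusted p = 0.000137, adjusted p = 0.0859 with an estimated correlation. For NF-kB targets and feedback 12 of 23 members rose and 11 did not pass (14 up adjusted over the list alone), fry adjusted p = 0.000494, adjusted p = 0.0911 with an estimated correlation. Among them were Ptgs2 (3.22 ± 0.31), which makes prostaglandins, and Nfkbiz (2.36 ± 0.20). For the inflammasome 5 of 10 members rose and 5 did not pass (6 up and 1 down adjusted over the list alone), fry adjusted p = 0.000382, adjusted p = 0.0911 with an estimated correlation. Among them were Casp4 (1.97 ± 0.14) and Nlrp3 (1.62 ± 0.18). Of conventional DC type 1 markers 2 of 12 members rose and 10 did not pass (2 up and 1 down adjusted over the list alone), fry adjusted p = 0.000263, adjusted p = 0.544 with an estimated correlation, with a median of -0.00422 against the direction of the test, Ifi205 being 1 of the 2 that rose. Of maturation and migration genes 4 of 23 members rose and 19 did not pass, among them Apol7c (1.58 ± 0.25) and Serpinb9 (1.11 ± 0.18) (fry adjusted p = 0.0873, and 0.0247 with the replicate block within cell type). For MHC class II presentation of the 12 measured members 12 did not pass, with 0 of them at an unadjusted limma p under 0.05 (fry adjusted p = 0.948). For phagocytic, scavenger and lectin receptors 6 of 28 members rose, 1 fell and 21 did not pass (fry adjusted p = 0.0555, and 0.00984 with the replicate block within cell type). Among them were Clec4e (3.38 ± 0.27) and Olr1 (2.47 ± 0.26). Mrc1 (2.44 ± 0.16), the mannose receptor, rose too. For stromal markers of the 9 measured members 9 did not pass, with 1 of them at an unadjusted limma p under 0.05 (fry adjusted p = 0.812), Col1a1 lying at 4.98 ± 0.0691 before and 4.90 ± 0.12 after LPS.

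LPS in GM-MF was compared with no LPS to ask the same of the macrophages. The rises included Il6 (74.3-fold, log2 6.21 ± 0.29, adjusted p = 3.42e-09), U90926 (62.5-fold, log2 5.97 ± 0.18), Hamp (52.8-fold, log2 5.72 ± 0.25), which encodes the iron hormone hepcidin, Il12b (38.7-fold, log2 5.27 ± 0.24), Nos2 (26.8-fold, log2 4.75 ± 0.44), Il10 (23.4-fold, log2 4.55 ± 0.21), Il19 (16.4-fold, log2 4.04 ± 0.15) and Il1f6 (15.7-fold, log2 3.97 ± 0.19), an interleukin-36. Il12a (9.05-fold, log2 3.18 ± 0.21), Ifnb1 (7.72-fold, log2 2.95 ± 0.22) and Il1b (4.88-fold, log2 2.29 ± 0.18) rose too. Ccr7 rose (2.47 ± 0.26) from 6.99 ± 0.58 to 9.45 ± 0.58, under the 12.05 ± 0.0455 of unstimulated GM-DC.

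In GM-MF 3461 genes passed, 1304 up and 2157 down (37.7% up, against 45.5% after median centring, 45.2% after quantile normalization and 52.4% after cyclic loess, which turns the balance), and 5362 had an unadjusted p under 0.05. At least 2-fold changes were found for 633 genes, 359 up and 274 down, and 106 genes changed at least 4-fold. The largest falls were Rab7b (7.45-fold, log2 -2.90 ± 0.12, adjusted p = 1.85e-09), a small GTPase of lysosomal traffic, Kcnj2 (-2.88 ± 0.25), a potassium channel, Cd300lb (-2.87 ± 0.21), Cxcr4 (-2.74 ± 0.12), a chemokine receptor, Mras (-2.64 ± 0.10), Gpr65 (-2.64 ± 0.23), an acid sensor, Slc43a2 (-2.43 ± 0.16) and Inpp5d (-2.41 ± 0.19), a phosphatase that limits PI3 kinase signalling.

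For cytokines 17 of 20 members rose and 3 did not pass (19 up adjusted over the list alone), median 1.92, fry adjusted p = 1.07e-06. For chemokines 14 of 20 members rose and 6 did not pass, median 1.30, fry adjusted p = 1.07e-06. Among them were Ccl7 (3.04 ± 0.26), Cxcl9 (2.76 ± 0.18), Cxcl1 (2.63 ± 0.25) and Ccl4 (2.45 ± 0.23). These lists were the 2 that held in camera with an estimated correlation, and fry passed 18 of 32 and camera with the preset correlation 13. For NF-kB targets and feedback 14 of 23 members rose and 9 did not pass (15 up and 1 down adjusted over the list alone), median 0.80, fry adjusted p = 3.22e-05, adjusted p = 0.0696 with an estimated correlation. Among them were Ptgs2 (3.79 ± 0.31) and Socs3 (2.94 ± 0.16), an inhibitor of cytokine signalling. For interferon-stimulated genes 19 of 30 members rose and 11 did not pass (23 up adjusted over the list alone), median 0.70, fry adjusted p = 0.000363, adjusted p = 0.119 with an estimated correlation. Among them were Iigp1 (2.73 ± 0.15) and Mx2 (1.81 ± 0.13). For costimulation 8 of 12 members rose and 4 did not pass (9 up adjusted over the list alone), fry adjusted p = 8.34e-05, adjusted p = 0.0911 with an estimated correlation. Among them were Cd80 (2.99 ± 0.14) and Cd40 (2.13 ± 0.20). Maturation and migration genes also rose in the macrophages: 11 of 23 members rose, 1 fell and 11 did not pass (13 up and 1 down adjusted over the list alone), median 0.71, fry adjusted p = 0.000198, adjusted p = 0.0953 with an estimated correlation. Serpinb9 (2.12 ± 0.18) was among them. For dendritic cell core genes 11 of 31 members rose, 2 fell and 18 did not pass (12 up and 3 down adjusted over the list alone), fry adjusted p = 0.0027, adjusted p = 0.184 with an estimated correlation. Hmgn3 (1.42 ± 0.13) was among them. Of MHC class II presentation genes 2 of 12 members fell and 10 did not pass (fry adjusted p = 0.182, and 0.012 with the replicate block within cell type). In the macrophage core list 3 of 35 members rose, 7 fell and 25 did not pass (4 up and 7 down adjusted over the list alone) (fry adjusted p = 0.431, and 0.0351 with that block). Mertk (0.97 ± 0.16) and Cd14 (0.79 ± 0.14) rose and Csf1r (-0.93 ± 0.12) and Fgd4 (-1.08 ± 0.19) fell.

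Cholesterol synthesis and uptake genes fell in GM-MF: 15 of 19 members fell and 4 did not pass (17 down adjusted over the list alone), median -1.18, fry adjusted p = 0.000198, adjusted p = 0.119 with an estimated correlation. Among them were Sqle (-1.52 ± 0.17), Hsd17b7 (-1.41 ± 0.16), Hmgcs1 (-1.38 ± 0.16) and Msmo1 (-1.34 ± 0.16), all enzymes of the pathway. In GM-DC 2 of 19 members rose, 2 fell and 15 did not pass (2 up and 3 down adjusted over the list alone) (fry adjusted p = 0.744). Dhcr7 (-0.82 ± 0.16) fell. Tricarboxylic acid cycle genes fell in GM-MF: 8 of 19 members fell and 11 did not pass (12 down adjusted over the list alone), median -0.31, fry adjusted p = 0.000401, adjusted p = 0.184 with an estimated correlation. Among them were Idh1 (-1.14 ± 0.12) and Aco1 (-0.95 ± 0.11). For the cell cycle 3 of 27 members rose, 10 fell and 14 did not pass (3 up and 14 down adjusted over the list alone), fry adjusted p = 0.0027, adjusted p = 0.184 with an estimated correlation, a call lost with median centring (adjusted p = 0.0508) and cyclic loess (adjusted p = 0.0633). Ccna2 (-0.97 ± 0.13) and Birc5 (-0.76 ± 0.11) fell and Tyms (1.75 ± 0.15) rose. Of neutrophil and granule markers 2 of 15 members rose and 13 did not pass (3 up adjusted over the list alone) (fry adjusted p = 0.00118, adjusted p = 0.184 with an estimated correlation), those that passed being Lcn2 (3.67 ± 0.13) and Camp (0.63 ± 0.13). Of mast cell and basophil markers 1 of 10 members rose and 9 did not pass (fry adjusted p = 0.0027, adjusted p = 0.363 with an estimated correlation), again Hdc (3.43 ± 0.17).

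The difference of the LPS responses asks whether dendritic cells and macrophages of these cultures respond to LPS differently. They did in 1514 genes, 904 with a more positive response in GM-DC and 610 with a more positive response in GM-MF, and 649 of them by at least 2-fold, 379 and 270, 136 by at least 4-fold (3676 at an unadjusted p under 0.05, and 307 with treat against 1.5-fold). Interferon-stimulated genes such as Ifit1 (15.7-fold, log2 3.97 ± 0.21, adjusted p = 1.51e-07), Xaf1 (3.84 ± 0.22), Rtp4 (3.81 ± 0.30) and Ifit2 (3.72 ± 0.24), and Slfn1 (4.10 ± 0.36), Ifi207 (3.94 ± 0.22) and Samd9l (3.83 ± 0.23) outside the list, had larger responses in GM-DC, where they started low, than in GM-MF, where they were high before LPS. Il6 (18.8-fold, log2 -4.23 ± 0.41, adjusted p = 1.26e-05), Nos2 (-3.63 ± 0.62), Il10 (-3.06 ± 0.29), Il12a (-2.81 ± 0.30), Il12b (-2.78 ± 0.35) and Ifnb1 (-2.02 ± 0.32) had larger responses in GM-MF. So did U90926 (-4.39 ± 0.25), Hamp (-4.05 ± 0.35), Il1f6 (-3.71 ± 0.28), Il19 (-3.56 ± 0.22), Penk (-3.27 ± 0.34), the precursor of enkephalin peptides, and Hdc (-3.11 ± 0.25), which makes histamine. Cd70 (3.12 ± 0.38), Tnfsf9 (2.18 ± 0.31), Ccl3 (3.20 ± 0.20), Tnf (1.74 ± 0.38) and Il23a (1.61 ± 0.29) responded more in GM-DC. Of these, Ccl3 and Tnf were higher in GM-MF before LPS, so their responses there started from a higher level. Among genes with larger responses in GM-MF, Il6 and Il12b were higher in GM-DC before LPS, so their responses in GM-MF started from a lower level. With LPS the level of Il12b did not pass between the cell types. Lrrc32 (3.76 ± 0.32) rose in GM-DC and fell in GM-MF. Costimulatory Cd40 had responses that differed by 0.0297 ± 0.28, Cd86 by 0.0731 ± 0.16 and Il1b by -0.21 ± 0.25, and none of these passed (adjusted p = 0.982, 0.897 and 0.763).

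Across the 19938 genes the responses correlated with Pearson's r = 0.395 and Spearman's rho = 0.32 (genes are not independent replicates), and r was 0.44 among genes with a mean above the median. Genes called and changed at least 2-fold in both cell types were up in both for 87, against 5.92 for independent lists, down in both for 35, against 1.18, and opposite for 9, against 6.07. Of 234 genes up at least 2-fold in GM-DC alone, 153 also differed at least 2-fold in the test of the responses, as did 177 of 271 up in GM-MF alone, 108 of 231 down in GM-MF alone and 23 of 50 down in GM-DC alone. For the rest of those genes a difference of at least 2-fold between the responses was not shown.

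In the lists a member is counted as up where its response was more positive in GM-DC, as tested by the difference. For interferon-stimulated genes 22 of 30 members were up, 2 were down and 6 did not pass, median 2.02, fry adjusted p = 0.000338, adjusted p = 0.323 with an estimated correlation. Iigp1 (-2.30 ± 0.21) and Mx1 (-0.64 ± 0.13) responded more in GM-MF. For cytokines 4 of 20 members were up, 9 were down and 7 did not pass (4 up and 11 down adjusted over the list alone), median -0.64, fry adjusted p = 0.00892, adjusted p = 0.323 with an estimated correlation. For cholesterol synthesis and uptake 12 of 19 members were up and 7 did not pass (14 up adjusted over the list alone), median 0.85, fry adjusted p = 0.00892, adjusted p = 0.323 with an estimated correlation. Among them were Stard4 (1.67 ± 0.19), Msmo1 (1.54 ± 0.22), Hsd17b7 (1.37 ± 0.22) and Hmgcs1 (1.34 ± 0.22). Chemokines went both ways: 5 of 20 members were up, 9 were down and 6 did not pass (6 up and 9 down adjusted over the list alone) (fry adjusted p = 0.572). Among them were Ccl3 (3.20 ± 0.20), Cxcl10 (2.24 ± 0.30) and Ccl2 (1.61 ± 0.29) on the side of GM-DC and Ccl8 (-2.63 ± 0.55) on that of GM-MF. Ccl3, Cxcl10 and Ccl2 were higher in GM-MF before LPS. Maturation and migration genes had more positive responses in GM-MF: 9 of 23 members were down and 14 did not pass (1 up and 10 down adjusted over the list alone), median -0.40, fry adjusted p = 0.0235, adjusted p = 0.323 with an estimated correlation. Among them were Ccr7 (-2.52 ± 0.37) and Cd200 (-1.21 ± 0.15), and that call was lost without any 1 of GM-DC LPS replicates 1 and 2 and GM-MF unstimulated replicates 1 and 3 (adjusted p 0.0519 to 0.0702). The mean level of this list before LPS was 10.19 ± 0.134 in GM-DC and 6.97 ± 0.161 in GM-MF. Compression of the signal near the top of the scale in GM-DC was not tested for it. Fry passed 12 of 32 lists and camera with the preset correlation 9, and with an estimated correlation camera passed 0 of 32, so none of these list calls holds there.

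**Figure D4:**
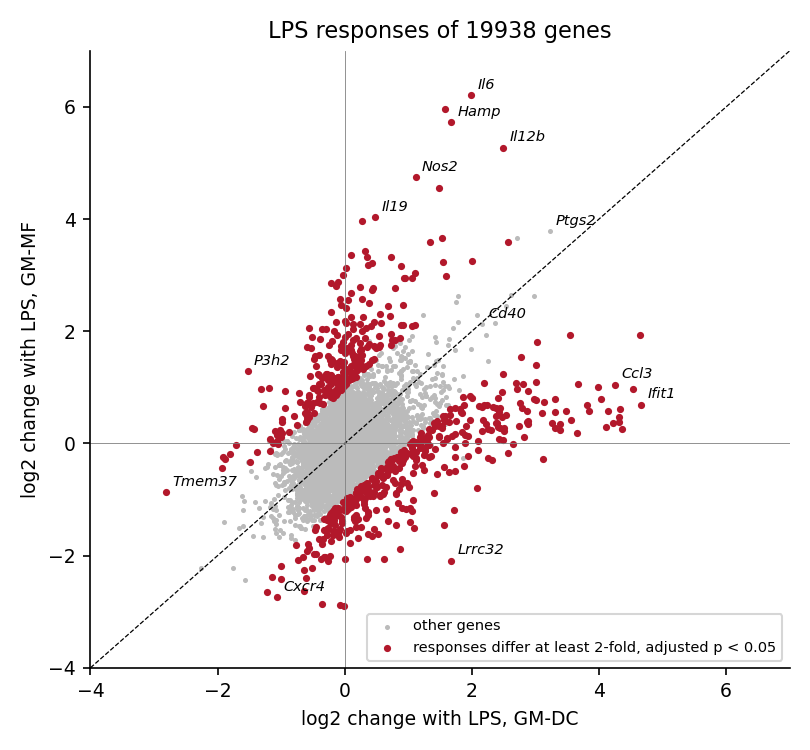
The log2 change with LPS of each of 19938 genes in GM-DC (horizontal axis) and GM-MF (vertical axis), the dashed line marking equal responses and red points the 649 genes whose responses differed at least 2-fold with an adjusted limma p under 0.05. Ifit1 and Ccl3 lie toward GM-DC, Il6, Hamp, Nos2 and Il19 toward GM-MF, Cd40 and Ptgs2 near the line, and Lrrc32 and P3h2 changed in opposite directions.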

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

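Of the tests in this part, the one on interferon-stimulated genes well under the top of the scale, both tests under cyclic loess and the one on cell cycle genes were chosen after the result was seen. Each SE in this part is a spread over genes. Genes that move together are not independent replicates, so it does not measure the spread between cultures and can be too small. The LPS responses of GM-DC and GM-MF differed by a test of the difference itself in 1514 genes, 649 of them by at least 2-fold. Of 200 distinct ways to split the labels 100 were drawn, the real one included. As many genes as the real split came from 3 of the 100, and as many with at least 2-fold from 4, shares under 0.05. Equal replicate numbers correlated within each cell type, and of the 32 splits that part all of these pairs 2 gave as many genes, and 3 as many with at least 2-fold. The highest counts of the other splits were 3979 and 1546, both from the split that reverses the labels in GM-MF throughout, which measures the sum of the responses, a structure of the samples. With that split counted, both shares of the 32 lie above 0.05. The next highest of the 32 gave 1400 and 726, fewer than the real split for all genes and more for those with at least 2-fold, and drawn splits that break pairs reached 1753 and 781. Splits that mix arrays with and without LPS put the LPS effect into the spread within groups, so their counts do not stand for equal responses. Chance is therefore not excluded by the 100 splits drawn, nor by the 32. Leaving out 1 array gave 1180 to 1748 genes, and 594 to 716 with at least 2-fold.

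For the other comparisons the 10 splits are too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many genes, and the highest other gave 0. For LPS within a cell type, where equal replicate numbers correlated, 4 of the 10 splits part all 3 pairs. The real values, all and with at least 2-fold, were 6827 and 2533 for the cell types before LPS, 7228 and 2572 with LPS, 1938 and 415 for LPS in GM-DC, and 3461 and 633 for LPS in GM-MF.

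Genes whose LPS responses differed are given with the log2 difference of the responses, GM-DC minus GM-MF, n = 3 arrays per group in the limma fit. A value above 0 can come from a larger rise in GM-DC or a deeper fall in GM-MF, and a value under 0 from the reverse. Above 0 were Slfn1 (4.10 ± 0.36), Ifit1 (3.97 ± 0.21), Ifi207 (3.94 ± 0.22), Xaf1 (3.84 ± 0.22), Samd9l (3.83 ± 0.23), Rtp4 (3.81 ± 0.30), Ifit2 (3.72 ± 0.24), Adgre1 (0.96 ± 0.19) and Tnf (1.74 ± 0.38). Above 0 lay also Il23a (1.61 ± 0.29), Cxcl10 (2.24 ± 0.30), Ccl2 (1.61 ± 0.29), Rab30 (1.41 ± 0.32), Fgl2 (1.20 ± 0.31), Cd70 (3.12 ± 0.38), Tnfsf9 (2.18 ± 0.31), Ccl3 (3.20 ± 0.20) and Acod1 (1.92 ± 0.29). The same sign had Bcl3 (1.11 ± 0.23), Clec4e (3.14 ± 0.37), Mrc1 (2.16 ± 0.23), Stard4 (1.67 ± 0.19), Msmo1 (1.54 ± 0.22), Hsd17b7 (1.37 ± 0.22), Hmgcs1 (1.34 ± 0.22), Mcm3 (1.51 ± 0.22) and Mki67 (1.20 ± 0.21). Further ones were Aco1 (0.71 ± 0.15), Idh1 (0.68 ± 0.17), Sdhb (0.52 ± 0.13), Egr2 (1.52 ± 0.19), Egr1 (2.35 ± 0.19), Ifi205 (2.71 ± 0.21) and Ccr2 (2.07 ± 0.18). Under 0 were U90926 (-4.39 ± 0.25), Il6 (-4.23 ± 0.41), Hamp (-4.05 ± 0.35), Il1f6 (-3.71 ± 0.28), Nos2 (-3.63 ± 0.62), Il19 (-3.56 ± 0.22), Penk (-3.27 ± 0.34), Hdc (-3.11 ± 0.25) and Ccr7 (-2.52 ± 0.37). Under 0 lay also Ccl22 (-1.29 ± 0.32), Csf1r (-0.69 ± 0.18), Il10 (-3.06 ± 0.29), Il12a (-2.81 ± 0.30), Il12b (-2.78 ± 0.35), Ifnb1 (-2.02 ± 0.32), Kit (-2.19 ± 0.29), Serpinb6b (-1.21 ± 0.31) and Cd200 (-1.21 ± 0.15). The negative sign had also Ccl8 (-2.63 ± 0.55), Iigp1 (-2.30 ± 0.21), Mx1 (-0.64 ± 0.13), Socs3 (-1.88 ± 0.22), Fcgr4 (-2.22 ± 0.37), Marco (-2.02 ± 0.32), Tyms (-1.03 ± 0.21), Il18 (-2.40 ± 0.31) and Il4ra (-0.86 ± 0.17). Others under 0 were Nr4a3 (-2.65 ± 0.43), Atf3 (-1.12 ± 0.23), Vcan (-2.31 ± 0.39) and Lcn2 (-2.14 ± 0.19). Genes that changed in opposite directions were Lrrc32 (3.76 ± 0.32), Ccnd1 (2.60), Fgr (2.90), Ncapg2 (2.08), Nrp1 (2.17), Nrros (2.25), P3h2 (-2.82), Plau (3.01) and Rasa3 (2.42). Some of these calls were lost without 1 array: Ccl22 without GM-DC LPS replicate 2, GM-DC unstimulated replicate 1, GM-MF LPS replicate 2 and GM-MF unstimulated replicate 1 (adjusted p 0.0515 to 0.0613), Csf1r without GM-DC LPS replicate 1, GM-DC unstimulated replicates 1 and 2, GM-MF LPS replicates 1 and 3 and GM-MF unstimulated replicates 1 and 2 (adjusted p 0.0519 to 0.0702), Serpinb6b without GM-DC LPS replicates 1 and 2, GM-DC unstimulated replicates 1 and 3, GM-MF LPS replicates 1 and 2 and GM-MF unstimulated replicate 1 (adjusted p 0.053 to 0.0645), Fgl2 without GM-DC LPS replicate 2, GM-MF LPS replicate 3 and GM-MF unstimulated replicate 2 (adjusted p 0.0635 to 0.073), Idh1 without GM-DC LPS replicate 1, GM-MF LPS replicate 2 and GM-MF unstimulated replicates 1 and 3 (adjusted p 0.0511 to 0.059) and Sdhb without GM-DC LPS replicate 2, GM-DC unstimulated replicates 1 and 2 and GM-MF LPS replicate 3 (adjusted p 0.051 to 0.0661). Calls were also lost with all probe sets for Rab30 (adjusted p = 0.0513), Csf1r (0.0599), Ccl22 (0.0809), Fgl2 (0.0891) and Serpinb6b (0.0929), and with eBayes with trend and robust for Ccl22 (adjusted p = 0.0615) and Fgl2 (0.0547). Idh1 lost its call with median centring (adjusted p = 0.0695) and Sdhb with cyclic loess (adjusted p = 0.0568).

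Lists whose responses differed by fry had these median differences: dendritic cell core -0.29, maturation and migration -0.40, cytokines -0.64, interferon-stimulated genes 2.02, NF-kB targets -0.25, cholesterol 0.85, cell cycle 0.26, tricarboxylic acid cycle 0.20, alternative activation 0.00309, immediate early -0.0377, neutrophil -0.34 and mast cell -0.16. The immediate early median has the sign opposite to the test. With an estimated correlation camera passed 0 of 32 lists in this comparison. The calls of these lists were lost without 1 array: dendritic cell core without GM-DC LPS replicates 1 and 2, GM-DC unstimulated replicates 1 and 3, GM-MF LPS replicates 1 and 2 and GM-MF unstimulated replicates 1 and 3 (adjusted p 0.0582 to 0.0728), maturation and migration without GM-DC LPS replicates 1 and 2 and GM-MF unstimulated replicates 1 and 3 (adjusted p 0.0519 to 0.0702), NF-kB targets without GM-DC LPS replicates 1, 2 and 3, GM-DC unstimulated replicates 1 and 3, GM-MF LPS replicates 1, 2 and 3 and GM-MF unstimulated replicates 1 and 3 (adjusted p 0.0639 to 0.113), cell cycle without GM-DC LPS replicate 1 (adjusted p = 0.055), tricarboxylic acid cycle without GM-DC LPS replicates 1 and 2, GM-DC unstimulated replicates 2 and 3, GM-MF LPS replicates 2 and 3 and GM-MF unstimulated replicates 1 and 3 (adjusted p 0.0531 to 0.0708), alternative activation without GM-DC LPS replicate 1, GM-DC unstimulated replicates 1, 2 and 3, GM-MF LPS replicates 1 and 3 and GM-MF unstimulated replicates 1, 2 and 3 (adjusted p 0.0519 to 0.0708), immediate early without GM-DC LPS replicates 1, 2 and 3, GM-DC unstimulated replicates 1 and 2, GM-MF LPS replicates 1, 2 and 3 and GM-MF unstimulated replicates 1, 2 and 3 (adjusted p 0.0582 to 0.112), neutrophil without GM-DC LPS replicates 1 and 2, GM-DC unstimulated replicate 3 and GM-MF unstimulated replicates 1, 2 and 3 (adjusted p 0.0534 to 0.0641) and mast cell without GM-DC LPS replicate 1 and GM-MF unstimulated replicate 3 (adjusted p 0.0519 to 0.0554). With the replicate block the calls of the dendritic cell core (adjusted p = 0.0731), NF-kB (adjusted p = 0.0999) and immediate early lists (adjusted p = 0.0546) were lost, and with the block within cell type that of NF-kB (adjusted p = 0.128). Median centring ended the calls of the cell cycle (adjusted p = 0.142), tricarboxylic acid cycle (0.209), alternative activation (0.12) and immediate early lists (0.0561). Cyclic loess ended those of the cell cycle (adjusted p = 0.0722) and immediate early lists (0.233), and quantile normalization those of NF-kB (adjusted p = 0.0685) and immediate early (0.153). Camera with the preset correlation did not pass alternative activation (adjusted p = 0.455), immediate early (0.417) and mast cell (0.0591).

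Interferon-stimulated genes had larger responses in GM-DC (fry adjusted p = 0.000338, adjusted p = 0.323 with an estimated correlation) and were already high in unstimulated GM-MF. Among the 12 of 30 members at least 3 log2 units under the top of the scale the median difference was 1.95 (SE 0.50), which argues against compression for these, while for the other 18 it cannot be told apart, since 2 of 1069 other genes with like starting levels rose as much. Against GM-MF carried over into the GM-DC LPS arrays as the whole cause, 10 macrophage core markers lay -1.54 (SE 0.34) from the change that the median share needed, 19.3%, would give. The median observed change of these markers was 0.40, and the shares needed ran from 0.664% to 89.9% between list members. A smaller carried-over share is therefore not excluded. With LPS 25 cytokine and NF-kB members rose at least 2-fold in GM-MF. Of these, 40% (exact binomial confidence interval 21.1 to 61.3) were already at least 2-fold higher in unstimulated GM-MF than in GM-DC. Another 5 were at least 2-fold higher in unstimulated GM-DC. The interval takes the members as independent, which genes that move together are not, and does not measure the spread between cultures. An LPS-like activation of GM-MF before LPS therefore cannot be told apart. The cell type itself remains open as an untested explanation.

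Of cholesterol synthesis and uptake genes 15 of 19 members fell and 4 did not pass (17 down adjusted over the list alone) with LPS in GM-MF and 2 of 19 members rose, 2 fell and 15 did not pass (2 up and 3 down adjusted over the list alone) in GM-DC, with a median difference of responses of 0.85 (fry adjusted p = 0.00892, adjusted p = 0.323 with an estimated correlation). Under cyclic loess the median in GM-MF was -1.06 (SE 0.11), against -1.18 as deposited, which argues against scaling. Cell cycle genes fell too, with a median of -0.35 (SD 0.54 over members), less than the -1.18 of the cholesterol list. As both lists fell, fewer cycling cells cannot be told apart as a part of the cause. A block of sterol-regulated transcription in GM-MF is a candidate explanation: 9 fatty acid genes had a median of -0.61 (SE 0.24) in GM-MF, but -0.46 in GM-DC, so it cannot be told apart from a change in both cell types. The cell type itself stays open, untested.

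Of dendritic cell maturation and migration genes 11 of 23 members rose, 1 fell and 11 did not pass (13 up and 1 down adjusted over the list alone) with LPS in GM-MF (fry adjusted p = 0.000198, adjusted p = 0.0953 with an estimated correlation). As the whole cause, GM-DC carried over into those arrays is argued against by 8 dendritic cell core markers. These lay -1.12 (SE 0.25) from the change that the median share needed by the 11 members that rose, 14.5%, would give. Members that did not rise were left out of that share, which can make it larger. The shares needed ran from 0.487% to 58.8% between members, and the full dendritic cell core list also rose. A smaller carried-over share is therefore not excluded. Under cyclic loess the median of the list was 0.79 (SE 0.17), which argues against scaling. A response of the macrophages remains a hypothesis, since it was found and tested on the same data.

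A signal also lay in data that the comparisons did not use. Of 12146 probe sets without a gene symbol, 653 and 760 differed at least 2-fold between the cell types without and with LPS, 75 and 166 changed at least 2-fold with LPS in GM-DC and GM-MF, and 99 differed in their responses.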

How the results depend on the processing

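The replicate block within cell type was chosen after seeing the data, and the other alternatives before the data were examined. Of 556 called results of named genes 374 were kept under every alternative run and 182 lost their call at least once, all of them with the test against 1.5-fold and 64 of them also under another alternative. Of 90 called lists 69 lost their call, all 69 with an estimated correlation in camera. The test against 1.5-fold asks more of each gene by construction and gave 2607 genes for the cell types before LPS, 2713 with LPS, 268 for LPS in GM-DC (267 with at least 2-fold), 496 in GM-MF and 307 for the difference of the responses (307 with at least 2-fold). Hk1 between the cell types before LPS changed sign with probe sets averaged, to -0.15 (adjusted p = 0.21). The probe sets of Hk1 that were not kept therefore lie, on balance, the other way from the kept one.

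The correlation of the LPS responses, 0.395, moved to 0.336 with all probe sets, 0.423 among genes with at least 3 arrays above the table median, 0.44 among genes with a mean above the median, 0.383 with quantile normalization and 0.384 with array weights. The cause was not tested. Without 1 array it was 0.367 to 0.407.

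Leaving out 1 array gave 6197 to 6940 genes for the cell types before LPS (2472 to 2580 with at least 2-fold), 6593 to 7407 with LPS (2526 to 2663), 1331 to 2009 for LPS in GM-DC (363 to 503), 2717 to 3623 in GM-MF (610 to 683) and 1180 to 1748 for the difference of the responses (594 to 716). With the replicate number as a block, a pairing the labels do not state, the counts were 7011, 7343, 2049, 3648 and 1652 in the same order. With that block within each cell type, the last 3 became 2355, 3981 and 1939. The share of called genes that were higher depended on scaling: 52.2%, 57.3% and 48.7% (median centring, quantile normalization, cyclic loess) before LPS, 51.1%, 56.9% and 48.7% with LPS, and 45.5%, 45.2% and 52.4% for LPS in GM-MF. No detection calls were used here, so genes near background were tested with the others.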

Other observations

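No test was added for this part, and its genes were picked after their values were seen. In 9 genes LPS changed expression at least 2-fold in opposite directions, given as the log2 change in GM-DC and in GM-MF. Ccnd1 (1.09 and -1.51), Fgr (1.72 and -1.18), Lrrc32 (1.67 and -2.09), Ncapg2 (1.07 and -1.01), Nrp1 (1.02 and -1.15), Nrros (1.05 and -1.20), Plau (1.56 and -1.45) and Rasa3 (1.03 and -1.39) rose in GM-DC and fell in GM-MF. P3h2 (-1.53 and 1.29) fell in GM-DC and rose in GM-MF.

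Ch25h, which makes 25-hydroxycholesterol, was lower in GM-DC before LPS (-4.44, adjusted p = 5.41e-11). It rose with LPS in GM-MF (2.19, adjusted p = 1.18e-06) and did not pass in GM-DC (0.0114, adjusted p = 0.99).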
